A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

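Budding yeast (Saccharomyces cerevisiae) total RNA was compared on 6 two-colour spotted arrays. Per the labels, each array set RNA of the temperature-sensitive yra1-1 mutant against RNA of a Yra1 wild-type strain, both from cells at 37 °C, with no common reference. The labels place the mutant RNA in channel 1 on arrays 1, 4 and 6 and in channel 2 on arrays 2, 3 and 5. The arrays fall on 4 labelled days, coded 1 to 4 here. Arrays 5 and 6 share day 1, arrays 1 and 3 share day 4, and in each of these pairs the mutant sits in opposite channels. The titles also give arrays 1 and 3 the same slide number, told apart by a letter. Each array counted as 1 replicate of a single group. No label says that the RNAs came from separate cultures, so the p-values of single features measure the spread between these arrays, which may be technical. The title of array 1 has the letters mex before the name of the mutant, which the other titles lack, and what they stand for is not given in the sources used here.

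The deposited values are log10 ratios, 1 per feature and array. The scale was read from the values, since it is not given in the sources used here. Between 38 and 338 values per array were exact log10 ratios of whole numbers with 1 term of 60 or less, within a relative tolerance of 1e-08, whereas base 2 gave at most 2 and base e at most 1. Image analysis, background treatment, filtering and normalization by the authors are not given in the sources used here, and neither is the channel in the numerator. Array medians of the deposited values ran from −1.18 to 1.24 on the log10 scale, so the columns had not been centred. Scanner intensities were not used here, and signal over background is unknown.

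The table held 7684 rows. The 1 row without a numeric identifier was left out and the rows of 3 repeated identifiers were averaged, which left 7680 features. The platform annotation gave 1 gene symbol for 6695 features, several for 0 and none for 985. The named features covered 5583 genes, of which 1100 had exactly 2 features and 4 had more, and 6690 named features matched the current gene table. Features of a gene were tested separately. Values were converted to log2 and each array was centred on its median.

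Before the data were examined, a rule was fixed for turning the arrays. Signs were to be turned by the labelled channel if deposited columns of opposite channel assignment correlated below 0 in the median and columns of the same assignment above 0. The rule was met, so the main contrast took the sign from the labelled channel. It was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with a term for the column sign as deposited in the same fit, on features with values on at least 4 arrays and at least 2 of each channel assignment. All tests are two-sided. Adjusted p-values are Benjamini-Hochberg values over all features and the threshold was 0.05. The second coefficient of the same fit, the columns as deposited, is reported as an alternative chosen after seeing the data. Under neither reading is the overall direction settled: the main contrast means mutant over wild type if the deposited ratios are channel 1 over channel 2, its inverse if they are channel 2 over channel 1, and a dye effect if the columns had already been turned. For the columns as deposited, mutant over wild type is likely at most, on the basis that the titles name the mutant first. Results are therefore given as the positive or negative side.

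The 25 gene lists were fixed before the data were examined and tested with limma camera at a preset correlation of 0.01, beside an estimated correlation, a rank-based version and fry. Camera compares the features of a list with all other features, so its p-values depend on the correlation assumed between features of a list. List tests used features with values on every array in the fit. Named genes follow a rule fixed at the same time. YRA1 is always named, then up to 10 genes on each side with the largest shifts among named genes that pass with the same sign on every array, and up to 2 passing members of each list on each side. If no gene passes, the 5 smallest p-values on each side are named as not passing, and 1 member with the smallest p may be given for a list without a passing member. Genes named outside this rule are said to be so. Coding length came from the current gene table (R64 assembly). Correlations between arrays and with length are across features, which are not independent replicates, and they were not tested.

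Identifier order followed the position on the slide, with similar values 1 and 20 identifiers apart. After this was seen, a neighbourhood correction was added, which subtracts the median of the features 1, 2, 20 and 21 identifiers away on either side. Other alternatives added after seeing the data left out values that are ratios of small whole numbers (product of terms below 10000000), values that repeat another feature of the same array to the last of 9 decimals, or unnamed features, averaged the features of a gene, and left out or turned over array 1. Turning over array 1 reversed its sign only in the term being tested and left the other term as it was. It is therefore a different model under each reading. Alternatives fixed earlier changed the dye term, centring, scaling, weights, filters, threshold, model and treatment of days, and left out each array in turn.

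The tests were tested on simulated data with the residual spread of these arrays. Of features changed by 1, 2 and 3 log2 units among 7680, the label-turned contrast on 6 arrays recovered 6.15%, 65.8% and 84.7%, and the columns as deposited recovered 4.11%, 69.5% and 92.6%, with 0 wrong signs. Among the unchanged features the label-turned contrast made 14 false calls, beside 4, 50 and 50 recovered features of the respective sizes, which is a larger share than the threshold of 0.05 allows, and the columns as deposited made 0. Each contrast was simulated with a single random draw, so the 14 against 0 false calls do not rank the readings. Camera called a simulated list of 40 features shifted by 0.5 and did not call an unshifted list. The simulated errors were independent between features, whereas neighbouring features of these arrays correlated at 0.416 to 0.523. The simulation therefore cannot show how often camera calls an unshifted list in these data. The number of arrays limits the precision. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.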

Results

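Gene expression was compared between the yra1-1 mutant and a Yra1 wild-type strain of budding yeast at 37 °C, the temperature the labels call non-permissive for the mutant. Yra1 is an RNA-binding mRNA export factor that works with Sub2, Mex67 and the THO complex. The data are log ratios of 7680 spotted features on 6 two-colour arrays, 3 with the mutant RNA labelled in channel 1 and 3 with it labelled in channel 2. Between 7625 and 7680 features had a value on each array, and the SD across features was 0.99 to 1.43 log2 units. Before centring, array medians ran from −3.91 on array 4 to 4.11 on array 3 (log2).

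Measurements of a gene were only loosely repeatable within an array. For the 1100 genes with 2 features at separate positions, the correlation of both features across genes was 0.147 on array 1, 0.267 on array 2, 0.175 on array 3, 0.436 on array 4, 0.600 on array 5 and 0.231 on array 6. Features 1 identifier apart, with or without a gene name, correlated at 0.416 to 0.523. On each array 433 to 766 values were identical to the last decimal to that of another feature, and 96.3% to 100% of these had their twin within 2 rows and 2 columns of a grid 20 identifiers wide, against 0% to 1.77% after shuffling. QDR1 and MET18, a drug transporter and an iron-sulfur assembly protein spotted next to each other, shared 1 value on each of 5 arrays.

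The mutated gene and the auxotrophic marker genes TRP1 and URA3 lay on 1 side of 0 on 5 arrays and on the other side on array 1. TRP1 and URA3 belong to the fixed list of strain markers, and outside the naming rule they were singled out after their values were seen. YRA1 lay at −1.39 on array 1 and at 3.07, 1.64, 1.21, 3.49 and 1.00 on arrays 2 to 6 (centred log2 ratio, columns as deposited). TRP1, a tryptophan synthesis gene used as a strain marker, lay at −3.48 on array 1 and between 2.76 and 4.16 on the other 5. URA3, a uracil synthesis gene used in the same way, lay at 3.19 on array 1 and between −5.92 and −2.21 on the others. Of the other 6 genes in that list, LYS2 had the same split, at −0.25 on array 1 and 0.19 to 1.60 on the others, whereas LEU2, HIS3, ADE2, CAN1 and MET17 did not. For example, LEU2 lay at −0.10 on array 1 and between −1.58 and 1.61 on the others. The labelled channel does not follow the signs of YRA1, TRP1 and URA3: arrays 4 and 6 share the assignment of array 1 and arrays 2, 3 and 5 have the opposite assignment. Turning by the labels gave TRP1 2 positive and 4 negative arrays, so under neither reading did all 6 arrays run alike for this gene. The allele is described as temperature-sensitive, so YRA1 RNA need not be lost in the mutant and its value checks no label.

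**Figure D1:**
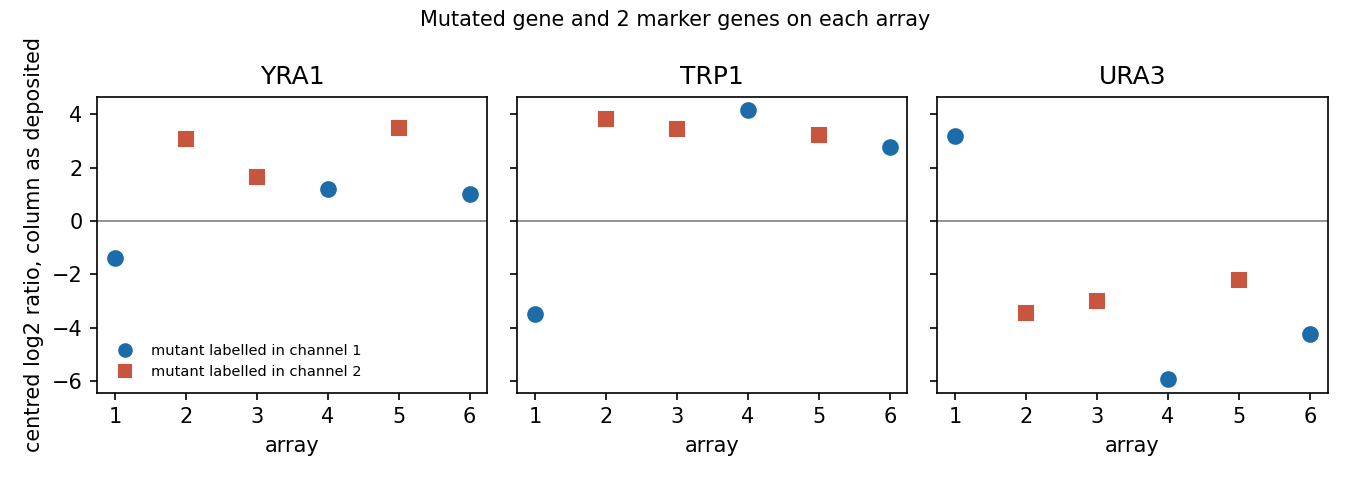
Centred log2 ratio of YRA1, TRP1 and URA3 (y axis, columns as deposited) on arrays 1 to 6 (x axis), with blue circles for arrays with the mutant labelled in channel 1 and red squares for channel 2. Array 1 lies on the other side of 0 from the other 5 arrays for each gene.

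The first comparison asks which genes differ between yra1-1 and wild type when signs are turned by the labelled channel. No named gene passed. The genes with the smallest p on the positive side were APP1 (2.03 ± 0.35, SE), RGL1 (1.81 ± 0.32), FDH1, formate dehydrogenase (1.79 ± 0.33), SMM1 (2.24 ± 0.42) and SSN3, the Mediator kinase (1.56 ± 0.30), each with limma adjusted p = 0.180 over 6 arrays. On the negative side they were PAB1, the poly(A)-binding protein (−1.75 ± 0.38, adjusted p = 0.180), UBC1, a ubiquitin-conjugating enzyme (−1.47 ± 0.34), HSP104, the heat shock disaggregase (−1.42 ± 0.34), and the ribosomal protein genes RPL11B (−1.27 ± 0.30) and RPS8B (−1.21 ± 0.30). UBC1, HSP104 and RPL11B had an adjusted p of 0.202 and RPS8B of 0.222. Of these 10 genes, SMM1 was the exception to the same turned sign on all 6 arrays, with 5 positive and 1 negative. FDH1 (feature 6310), SSN3 (6328) and RGL1 (6331) lay near one another on the slide by identifier, so they need not be separate gene effects. YRA1 was at −1.23 ± 0.42 with 4 of 6 arrays negative (adjusted p = 0.280). TRP1 was at −1.18 ± 0.75 (adjusted p = 0.573) and URA3 at 0.28 ± 0.88 (adjusted p = 0.950).

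By limma, 1 of 7680 features passed on the positive side and 0 on the negative side, while 998 (13.0%) had an unadjusted p under 0.05. The feature that passed has no gene name here and was singled out after its values were seen. It is feature 6467, at 4.61 ± 0.46 (SE, 5 arrays, adjusted p = 0.00862), and it has no value on array 1. It no longer passed without array 5, and without array 4 or 6 it had too few arrays to be tested. Without centring, the median of all features moved to −2.07 and 4887 features passed, 1 positive and 4886 negative, so every side given here is relative to the array medians.

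The same fit gives the shift in the columns as deposited, a reading added after the data were seen. There 127 features passed, 44 positive and 83 negative, of which 88 are named, and 1034 had an unadjusted p under 0.05. The largest shifts on the positive side were SPP1, a subunit of the histone methyltransferase complex COMPASS (2.57 ± 0.50, adjusted p = 0.0293), YER137C (2.36), the mitochondrial ribosomal protein gene MRPL38 (2.27 ± 0.37, 5 arrays, adjusted p = 0.0173), TIS11, an mRNA-decay factor of the iron response (2.22 ± 0.33, adjusted p = 0.0111), and CAF4 (2.17). RPL22B (2.09), YFL040W (2.00), the peroxisomal import receptor gene PEX9 (1.98), the allantoate permease gene DAL5 (1.88) and LOT6 (1.81) followed. On the negative side the largest were LOH1 (−3.26 ± 0.38, adjusted p = 0.0103), GUP2 (−2.75 ± 0.38, adjusted p = 0.0111), PIH1 (−2.65 ± 0.36, adjusted p = 0.0111) and FLO11, a cell surface flocculin (−2.62 ± 0.31, adjusted p = 0.0103). PEX31 (−2.57), CWC23, a splicing-linked J protein (−2.50), NIP100, a dynactin subunit (−2.49), QDR1 (−2.41), MET18 (−2.39) and APM2 (−2.38) followed. These 20 genes had the same sign on every array with a value. Several were neighbours on the slide by identifier, so they need not be separate gene effects. QDR1 (feature 3122), MET18 (3123), FLO11 (3143) and LOH1 (3163) lay close together on the grid 20 identifiers wide. So did APM2 (2626) and PIH1 (2646), NIP100 (6345) and GUP2 (6347), CWC23 (5243) and PEX31 (5261), and RPL22B (2469) and YFL040W (2470). SPP1 owes much of its size to array 1, where it lay at 6.71, against 0.75 to 2.68 on the others.

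These passing features did not carry over to the other feature of the same gene. Of the 127, 34 belong to a gene with exactly 2 features, and the other feature lay on the same side for 12. VAM7, a vacuolar fusion protein gene singled out after its values were seen, had both its features passing on opposite sides, at 2.27 ± 0.49 (adjusted p = 0.0433) and −2.09 ± 0.37 (adjusted p = 0.0208). The other features of TIS11 (−0.13), MRPL38 (−0.14), CAF4 (−0.85), CWC23 (0.55) and PEX31 (0.34) had the opposite sign to the feature that passed, and LOT6 (0.93) had the same sign. At least 1 repeated value was present in 58 of the 127 passing features (45.7%) and in 1162 of the other 7553 (15.4%, Fisher's exact test, two-sided, p = 1.41e-15, features not being independent). Ratios of small whole numbers went the other way, with at least 1 in 8 of the 127 passing features and in 61.6% of the others. After the neighbourhood correction 3 features passed, 2 of them among the 127, and 0 passed without array 4, without array 6 or with arrays of a day averaged (817, 783 and 888 at an unadjusted limma p under 0.05).

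**Figure D2:**
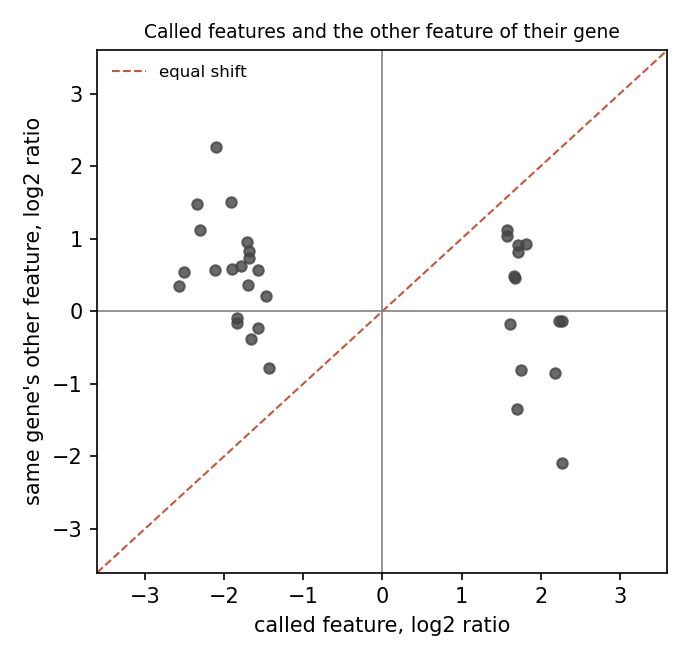
Log2 ratio of the gene's other feature (y axis) against that of the called feature (x axis), columns as deposited, for the 34 called features whose gene has exactly 2 features, with the dashed line marking equal shifts. For 12 of the 34 features the other feature lies on the same side of 0.

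Without array 1, TRP1 and URA3 passed in the columns as deposited, along with the small heat shock gene HSP12. The fit without array 1 was singled out after TRP1 and URA3 were seen on the other side of 0 there. That both pass largely restates this. HSP12 also lay on the other side of 0 on array 1, so leaving this array out favoured it too. TRP1 stood at 3.48 ± 0.39 (SE, 5 arrays, adjusted p = 0.00585), URA3 at −3.99 ± 0.41 (adjusted p = 0.00519) and HSP12 at 1.96 ± 0.38 (adjusted p = 0.0493), each with the same sign on all 5 arrays. YRA1 stood at 1.92 ± 0.40 with 5 of 5 arrays positive (adjusted p = 0.0661) and the small heat shock gene HSP26, singled out after its values were seen, at 2.24 ± 0.47 (adjusted p = 0.0655), and neither passed. In this fit 45 features passed, 16 positive and 29 negative, and 41 of them were among the 127. Over all 6 arrays TRP1 was at 2.32 ± 0.75 (adjusted p = 0.167), URA3 at −2.61 ± 0.88 (adjusted p = 0.185) and the adjusted p of YRA1 was 0.107. With the neighbourhood correction and without array 1, TRP1 was at 3.49 ± 0.38 and URA3 at −3.92 ± 0.40, both with an adjusted p of 0.0728, and 0 features passed in limma, with 910 at an unadjusted p under 0.05.

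The second comparison asks whether fixed groups of genes shifted together. In the contrast turned by the labels, 9 lists passed camera, all on the negative side: cytosolic ribosomal proteins by a mean of −0.65 log2 (149 of 165 features negative, camera adjusted p = 1.21e-23) and glycolysis and fermentation by −0.91 (34 of 35 negative, camera adjusted p = 1.47e-13). Heat shock proteins and chaperones had a mean of −0.46 (40 of 56 negative, camera adjusted p = 5.16e-07) and cell wall integrity genes of −0.38 (34 of 47, camera adjusted p = 0.000128). Amino acid biosynthesis (−0.30, 51 of 71 negative, camera adjusted p = 0.000362), the proteasome and Rpn4 targets (−0.29, 35 of 51, adjusted p = 0.000512) and ergosterol synthesis (−0.27, 27 of 37, adjusted p = 0.00185) also passed. The environmental stress response genes (−0.16, 61 of 103 negative) and the strain background and marker genes (−0.54, 8 of 9 negative) passed with a camera adjusted p of 0.0176 each. The estimated correlation ran from −0.046 for the strain markers to 0.519 for ribosomal proteins and 0.637 for glycolysis, against the preset 0.01. With an estimated correlation none of the 9 passed: camera adjusted p = 0.414 for the cell wall genes and adjusted p = 0.341 for each of the other 8. Fry called 0 lists. Without values that are ratios of small whole numbers camera called 4: ribosomal proteins, glycolysis, amino acid biosynthesis and the cell wall genes. There the mean changed sign for the stress response genes (0.066) and the proteasome (0.014), which did not pass. With the arrays of a day averaged the stress response genes (−0.10, camera adjusted p = 0.0812) and the strain marker genes (−0.50, adjusted p = 0.0722) no longer passed. With array 1 turned over, added after the data were seen, the proteasome (−0.12, camera adjusted p = 0.211), the stress response genes (−0.024, adjusted p = 0.713) and the strain marker genes (−0.33, adjusted p = 0.202) no longer passed. There the phosphate response (−0.29, camera adjusted p = 0.0142), ribosome biogenesis (−0.13, adjusted p = 0.0417) and sulfur assimilation (−0.25, adjusted p = 0.0417) newly passed, with an adjusted p of 0.590, 0.727 and 0.704 with an estimated correlation. With array weights the cell wall genes (−0.17, camera adjusted p = 0.0539) and the strain marker genes (−0.50, adjusted p = 0.0503) no longer passed.

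No single member of these lists passed over all features. The member with the smallest p in the amino acid list lay on the other side from its list: SNZ1, a vitamin B6 synthesis gene, at 1.32 ± 0.32 with 5 of 6 arrays positive (adjusted p = 0.212). In other lists these members were RPL11B (−1.27), the hexokinase gene HXK2 (−1.26 ± 0.38, adjusted p = 0.254), HSP104 (−1.42, its other feature −1.29 ± 0.34 with adjusted p = 0.234), the proteasome ATPase gene RPT3 (−1.20 ± 0.32, adjusted p = 0.234), ERG20 (−1.11 ± 0.31, adjusted p = 0.247), PNC1 in the stress response (−1.15 ± 0.33, adjusted p = 0.249), CRH1 in the cell wall list (−0.97 ± 0.34, adjusted p = 0.286) and YRA1 among the strain markers. Adjusted over the list alone, 0 members passed in any of the 9 lists. In other lists 1 member passed when adjusted over the list alone: PAB1 among mRNA export factors, RPA190, the largest RNA polymerase I subunit (1.70 ± 0.39), and PRM4 among mating genes (1.38 ± 0.32).

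The largest means of ribosomal protein and glycolysis genes were on array 5. Without it the turned mean went from −0.65 to −0.36 for ribosomal proteins (camera adjusted p = 4.19e-10) and from −0.91 to −0.44 for glycolysis (camera adjusted p = 5.87e-06), and neither passed with an estimated correlation (adjusted p = 0.489 each). Without array 5 the cell wall genes (−0.15, camera adjusted p = 0.0597), the stress response genes (−0.11, adjusted p = 0.0770) and the strain marker genes (−0.45, adjusted p = 0.0817) no longer passed, and without array 1 the stress response genes did not (−0.095, adjusted p = 0.132). Ribosomal protein genes had a mean of 1.97 on array 5 as deposited, 0.17 on array 2 and 0.29 on array 3, against −0.39, −0.34 and −0.74 on arrays 1, 4 and 6. Glycolysis genes had a mean of 2.85 on array 5, −0.18 on array 2 and 0.24 on array 3, against −0.39, −0.98 and −1.19 on arrays 1, 4 and 6. Within day 1, the turned mean was −1.36 for ribosomal proteins, −2.02 for glycolysis and −0.70 for heat shock genes, and within day 4 it was −0.34, −0.31 and −0.49. For the cell wall genes it was −0.90 within day 1 and −0.02 within day 4, and for the proteasome −0.03 and −0.49. In the same order it was −0.29 and −0.18 for amino acid synthesis, −0.15 and −0.24 for ergosterol synthesis, −0.22 and −0.31 for the stress response and −0.63 and −0.60 for the strain markers.

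**Figure D3:**
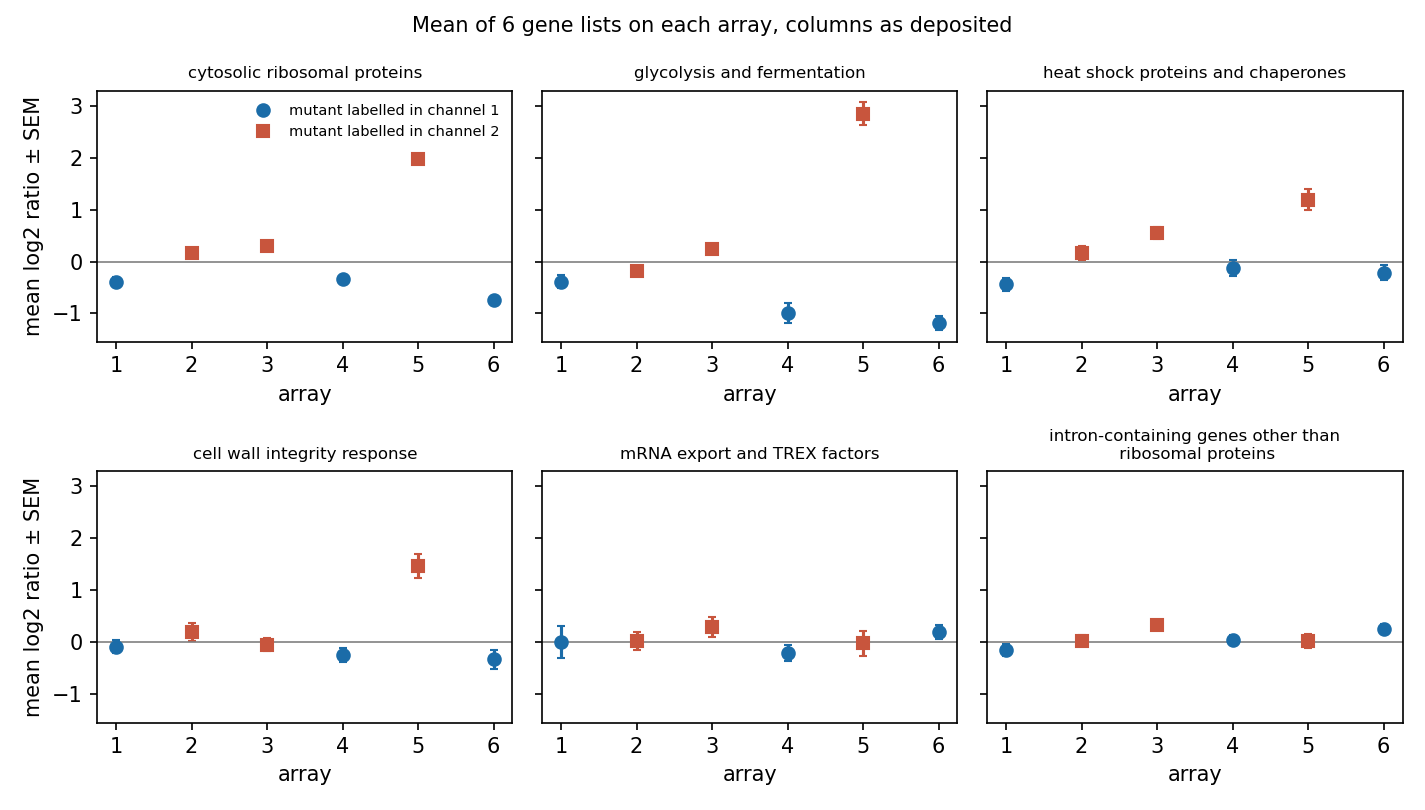
Mean centred log2 ratio of 6 gene lists (y axis, columns as deposited, bars give the SEM over features) on arrays 1 to 6 (x axis), with blue circles for the mutant labelled in channel 1 and red squares for channel 2. Ribosomal protein genes lie above 0 on the channel 2 arrays, from 0.17 to 1.97, and below 0 on the channel 1 arrays.

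Lists closer to the known role of Yra1 did not pass in the turned contrast. The mean was −0.07 for mRNA export and TREX factors (19 of 42 negative, camera adjusted p = 0.607), 0.20 for splicing factors (adjusted p = 0.143), 0.17 for the nuclear exosome and RNA surveillance (adjusted p = 0.363) and −0.04 for intron-containing genes outside the ribosomal proteins (adjusted p = 0.447). Respiration and the TCA cycle (−0.15, adjusted p = 0.0666), core and linker histones (−0.23, adjusted p = 0.143), mating and pheromone response (0.23, adjusted p = 0.187), G2/M genes (−0.13, adjusted p = 0.219) and phosphate response (−0.11, adjusted p = 0.337) did not pass either. With the neighbourhood correction, added after the data were seen, splicing factors (mean 0.17, 58 of 84 features positive) and core and linker histones (−0.37, 8 of 10 negative) passed with a camera adjusted p of 0.0077 each (adjusted p = 0.289 and 0.308 with an estimated correlation), and the strain marker genes did not pass (adjusted p = 0.197). Mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, sulfur assimilation, G1/S genes, markers of cell and mating type and the iron regulon had a camera adjusted p of 0.607 to 0.901. The signs of mean, median and camera statistic were not the same for mRNA export factors, intron-containing genes, mitochondrial ribosomal proteins, ribosome biogenesis, sulfur assimilation, G1/S genes, cell and mating type markers and the iron regulon.

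In the columns as deposited 0 of the 25 lists passed. The lowest camera adjusted p was 0.330, for cytosolic ribosomal proteins (mean 0.16, 124 of 165 features positive), and without array 1 it was 0.121, for sulfur assimilation (mean −0.41, 21 of 30 negative). Single members passed in 8 lists. They were RPL22B among cytosolic ribosomal proteins, MRPL38 on the positive and MRP51 (−2.25 ± 0.33) on the negative side among mitochondrial ribosomal proteins, TIS11 in the iron regulon, PSP2 (1.58 ± 0.33) and BET4 (−1.89 ± 0.33) among intron-containing genes, PRP18 (−1.47 ± 0.33) among splicing factors, ROK1 (−1.68 ± 0.36) in ribosome biogenesis, LYS5 (−1.69 ± 0.32) in amino acid synthesis and TIR3 (−1.83 ± 0.40) in the cell wall list. Of these, PRP18, ROK1 and LYS5 have another feature, at 0.22, 0.83 and 0.36, with the opposite sign, and that of PSP2, at 1.11, had the same sign. The other features of MRPL38 (−0.14) and TIS11 (−0.13) had the opposite sign too.

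Because the THO and TREX complexes act on long genes, the ratio was set against coding length across 6669 features. Spearman's rho was 0.061 in the turned contrast and −0.101 in the columns as deposited. By array it was 0.101, 0.017, −0.088, −0.169, −0.136 and 0.043 on arrays 1 to 6, so the sign differed between arrays of both channel assignments. In the turned contrast rho was 0.0054 without array 1.

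The arrays correlated weakly with one another. Across features, Pearson's r between arrays of the same channel assignment had a median of 0.259 (6 pairs, 0.042 to 0.386), and between opposite assignments a median of −0.035 (9 pairs, −0.135 to 0.326, 6 below 0). Set against the other feature of the same gene, which lies elsewhere on the slide, the medians were 0.029 and −0.107 across 1100 genes. The lowest of these were the pairs that share a day, at −0.261 for arrays 1 and 3 and −0.296 for arrays 5 and 6. The opposite-channel median that met the turning rule became 0.0096 after the neighbourhood correction and 0.125 without ratios of small whole numbers, both added after the data were seen.

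**Figure D4:**
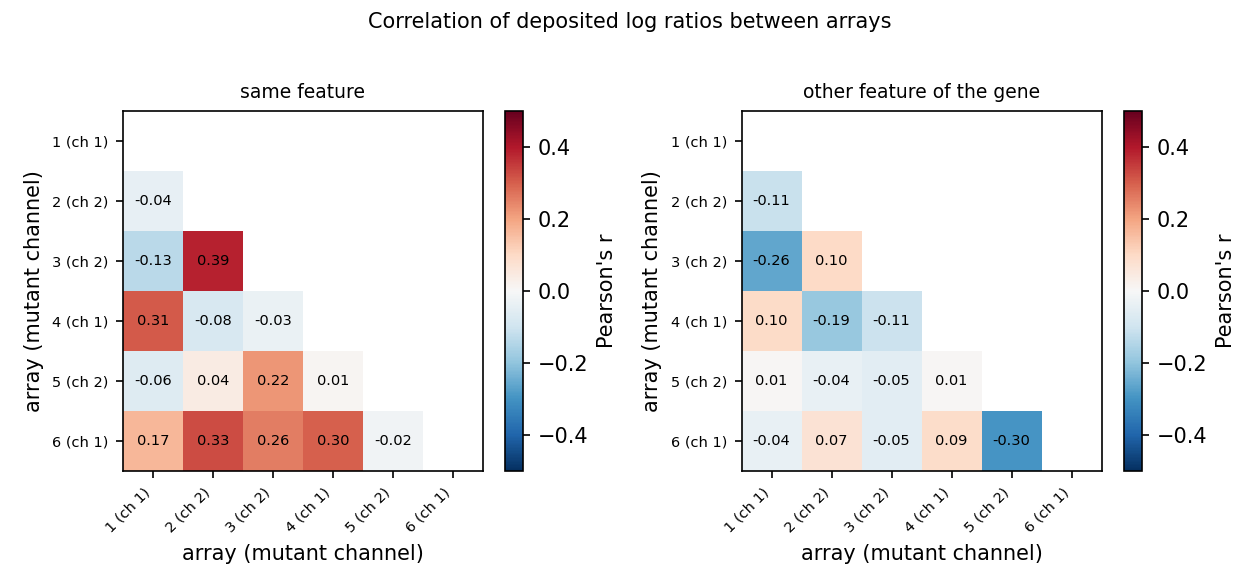
Pearson's r between each pair of arrays (axes give the array and the channel labelled as mutant), for the same feature on both arrays (left) and for different features of the same gene (right). The r of arrays 5 and 6, which share a day, is −0.018 on the left and −0.296 on the right.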

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

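The tests of array 1, the test of a dye effect and the count of patterns that turn whole days were chosen only after the results were seen, and so was the reading of the columns as deposited.

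Of 123 sets of array values that were checked, 10 held an array far from the others, where chance flags about 1 in 20 independent groups. The sets are not independent, since each list was checked both as deposited and turned, and some sets left out array 1. Array 5 was the array apart in 7 of the 10, where the cell wall and G1/S lists each count under both readings. As deposited, TRP1 lay at −3.48 on array 1 (the others 2.76 to 4.16, gap over range 0.817) and SPP1 at 6.71 on array 1 (the others 0.75 to 2.68, gap over range 0.676). Turned by the labels, UBC1 lay at −2.89 on array 5 (the others −1.41 to −0.88, gap over range 0.737). The turned mean of cytosolic ribosomal proteins was −1.97 on array 5 (the others −0.74 to −0.17, gap over range 0.684). The mean of glycolysis and fermentation genes as deposited was 2.85 on array 5 (the others −1.19 to 0.24, gap over range 0.648). The mean of cell wall integrity genes on array 5 was 1.47 as deposited (the others −0.33 to 0.19, gap over range 0.709) and −1.47 turned (the others −0.33 to 0.05, gap over range 0.751). The mean of G1/S genes on array 5 was −0.40 as deposited (the others −0.05 to 0.07, gap over range 0.734) and 0.40 turned (the others −0.07 to 0.04, gap over range 0.768). The turned mean of sulfur assimilation genes was −1.28 on array 4 (the others 0.06 to 0.38, gap over range 0.807).

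TRP1, URA3 and YRA1, singled out after their values were seen, lay on the opposite side on array 1 from the other 5 columns. A trend of spot position on array 1 is argued against, since the neighbourhood correction left 3 of 3 genes on their side (TRP1 −2.86, URA3 3.41, YRA1 −3.22), with a median ratio of the size after to before of 1.07. A reversed label or column of array 1 would turn all genes, and across 1094 genes the shift on arrays 2 to 6 correlated at −0.072 with the gene's other feature on array 1 (permutation p = 0.00073, two-sided, genes not being independent), or −0.137 with the neighbourhood correction, without a test. The sign goes with a reversal, but the size of the tested value is small. It could hardly be large, since the 2 features of a gene correlated at only 0.147 on array 1 itself. Whether the label or column of array 1 is reversed therefore stays open. Its title has the letters mex before the name of the mutant, so a different strain pair on array 1 stays open too, and neither this nor a biological explanation was tested.

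The 127 features that passed in the columns as deposited had a median size of 1.92 log2, and the neighbourhood correction left 1.09. A shift of the gene itself should appear in its other feature, which lies elsewhere on the slide, but the median ratio of the other feature to the passing one was −0.181 over 34 features. A position effect on the slide, repeated from array to array, would give such a ratio. Noise in features picked for large shifts would too, since a gene's 2 features correlated at only 0.147 to 0.600 within an array. This value therefore cannot single out position. Other values go with position: 57 of the 127 had another passing feature 1 identifier away, and 3 features passed after the neighbourhood correction. Repeated values, which lie close together on the slide, were present in 45.7% of the passing features and 15.4% of the others. Noise that is independent between features would not set passing features side by side, but no chance level for the 57 was computed. Of the 32 sign patterns of the 6 arrays, 1 gave as many features, the real one (127, highest other 2), but the arrays fall on 4 days, and turning whole days leaves 8 patterns (highest other 0), too few for a share under 0.05. A change between mutant and wild type remains open for single genes.

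In the contrast turned by the labels, 9 lists lay on the negative side. A dye effect on the transcripts of a list and a change in the mutant cannot be told apart, since it is not recorded whether the columns had been turned before they were deposited: if they had, this contrast holds the dye effect, and if not, the difference between the strains. Over arrays 2 to 6 TRP1 stood at −0.021 ± 0.39 (SE) turned by the labels and at 3.48 ± 0.39 as deposited, and URA3 at −1.10 ± 0.41 turned and at −3.99 ± 0.41 as deposited. The larger part of both genes followed the columns, but the turned value of URA3 lies more than 2 SE from 0, and on array 1 both genes had the opposite sign, so the test decides nothing. The 10 splits into 3 and 3 arrays are too few for a share under 0.05: 2 of them gave at least the 9 lists of the real split (highest other 11), and for features passing 1 of them did, the real one with 1 feature (highest other 0). Every other split gave at least 4 lists.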

How the results depend on the processing

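The reading of the columns as deposited, with all its alternatives, and the alternatives with the neighbourhood correction, weak spots (ratios of small whole numbers), repeated values, named features, averaged genes and array 1 turned over were chosen only after the results were seen. For single genes and lists, 851 alternative values kept their direction and side of the threshold, 250 no longer passed, 30 newly passed, 16 reversed and 2 without a test moved. For counts and correlations, 78 stayed close, 50 moved and 2 reversed. Except where the alternative has fewer features, fewer arrays or a stricter threshold, the cause was not tested. Signal over background is not known, so what weak signal limits could not be measured.

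Features passing in the contrast turned by the labels numbered 1, and 4887 with values not centred, 2 with arrays scaled to one spread, 2 with robust eBayes, 7 with array weights, 0 with features on all 6 arrays, 236 without the tenth of features with the largest residual spread, 0 in the unmoderated model, 0 to 4 without each array in turn, and 0 each with the neighbourhood correction, without repeated values, with named features only, with the features of a gene averaged, and with the neighbourhood correction and array 1 left out or turned over.

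Features passing in the columns as deposited numbered 127, and 2 with values not centred (both negative), 580 with array weights, 513 without the tenth of features with the largest residual spread, 0 with arrays of one day averaged, 257 with day as a random block, 0 in the unmoderated model, 0 at an adjusted p under 0.01, 0 to 214 without each array in turn, 3 with the neighbourhood correction, 36 without repeated values and 22 with the features of a gene averaged. With array 1 turned over 2 passed, TRP1 and URA3, and 2 with the neighbourhood correction as well, whereas 0 passed with the neighbourhood correction and array 1 left out. TRP1 and URA3 had already been seen on the other side of 0 on array 1, so that they pass when it is turned over largely restates this.

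Lists passing in the turned contrast numbered 9, with 0 under an estimated correlation, 0 by fry, 7 with array weights, 7 with arrays of one day averaged and 4 without weak spots, where the means of the stress response (0.066) and proteasome (0.014) lists changed sign and the strain marker list had too few features to be tested. With the neighbourhood correction camera called 10, 1 of them positive, with splicing factors and the core and linker histones gained and the strain marker genes lost, and fry called 1, ergosterol synthesis (fry adjusted p = 0.0223). In the columns as deposited they numbered 0, with 0 to 3 without each array in turn, 1 with the neighbourhood correction (ribosomal proteins, adjusted p = 0.0242, and 0.972 with an estimated correlation), 1 with it and array 1 left out (sulfur assimilation, adjusted p = 0.0059, and 0.973 with an estimated correlation), 6 with array 1 turned over and 5 with the neighbourhood correction and array 1 turned over.

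Turned genes that reversed were, with values not centred, APP1 (−0.078), RGL1 (−0.30), FDH1 (−0.32), SSN3 (−0.55) and URA3 (−1.83). TRP1 reversed with array 1 turned over (0.85), with the neighbourhood correction as well (0.96), and with that correction and array 1 left out (0.19). URA3 reversed in the same settings (−1.86, −1.89 and −1.11), without array 1 (−1.10, with 1.18 as the highest value without each array in turn), with arrays of one day averaged (−0.10) and within day 1 (−1.02). As deposited, TRP1 (−0.016) and URA3 (0.094) reversed within day 4, which holds array 1.

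The median correlation of opposite channel assignments, −0.035, reversed to 0.0096 with the neighbourhood correction and to 0.125 without weak spots. That of the same assignment, 0.259, moved to 0.029 with the other feature of the gene. Spearman's rho with coding length, 0.061, ran from 0.0054 to 0.135 without each array in turn.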

Other observations

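HSP12 and HSP26, which encode small heat shock proteins, were chosen after their values were seen, and the fixed list of heat shock proteins and chaperones did not pass in the columns as deposited (camera adjusted p = 0.380). HSP12 lay at −1.61 on array 1 and at 1.96, 1.94, 1.36, 1.75 and 2.73 on arrays 2 to 6 (centred log2, columns as deposited). HSP26 lay at −1.83 on array 1 and at 0.95, 2.63, 3.25, 3.19 and 1.19 on arrays 2 to 6.

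LOH1 and FLO11, spotted 20 identifiers apart, held an identical value on 2 arrays. Ratios of small whole numbers made up 36.8%, 33.2%, 5.78%, 14.0%, 9.99% and 7.60% of the values on arrays 1 to 6. Of the 127 features that passed as deposited, 57 had another passing feature 1 identifier away.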
